A study of Homo sapiens with 30 samples.

How the data were processed

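Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed in HEK293T cells, an established human embryonic kidney line, in which CTCF had been edited for auxin-inducible degradation. The cells carried transfected plasmids that supply the 2 parts of the degradation system. Per the labels' protocols, they were then kept for 72 h in medium with 0.5 mM of the auxin indole-3-acetic acid (IAA) or in medium without it. One label names the cells without IAA as treated with DMSO, while the protocol names only medium without IAA, so these cells are called "without IAA" here. Antibodies against CTCF, MBD3, TET1 and TET2 were used. With the inputs this gives 10 groups of 3 samples, 30 samples in all. Each sample was put in its group by its title.

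The deposited files are 8 peak lists, 1 for each antibody and condition. The 3 samples of a group were pooled by the authors before the peaks were called, and the lists hold no value per sample. The submitters' processing notes name FastQC 0.11.7, Bowtie2 2.3.4, SAMtools 1.9, MACS2 2.1.2, bedtools 2.25.0 and the genome build hg19, without saying which step each served. The control behind each list is not given in the sources used here. Column 7 of each list holds the fold enrichment of the peak, a ratio computed by the authors' peak caller, and column 9 holds −log10 of the q-value, also as deposited. The highest q in any list was 0.05. Column 10 gives the offset of the summit. Fold enrichment and q are the authors' values and were used only to describe, rank or filter peaks within 1 list, never to compare 2 lists. Regions are called strong or weak by fold unless −log10 q is named. The number of reads behind each list is unknown. It decides how many weak peaks reach the threshold, and a list can be longer or shorter for that reason alone.

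Rows of 1 list that shared at least 1 bp were joined into 1 region, which kept the highest fold, the highest −log10 q and the summit of the row with the highest −log10 q. A region was counted as shared with another list when the regions had at least 1 bp in common. A region called without IAA is described as kept when it shared a base with a region of the same antibody with IAA, and otherwise as no longer called. Regions are described as at CTCF when they shared a base with a CTCF region of cells without IAA, and as away from CTCF otherwise. Shares carry Wilson 95% intervals, which cover counting error over regions only.

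Sharing between lists was compared with 1000 random circular shifts of 1 list along each chromosome, with a one-sided permutation p and the fold over the mean of the shifts. The chromosome length used for the shifts was the highest position in any of the 8 lists, since the hg19 sequence was not used here. Differences in loss or in location between classes of regions were tested with Fisher's exact test, two-sided, and given as odds ratios with 95% intervals, after adding 0.5 to each cell of a table with a 0. Medians of fold were compared with a two-sided permutation test of 100000 random splits. Where several tests asked the same question, the Benjamini-Hochberg adjustment was made over that family. Regions are positions, not replicates, so every p-value is about where regions lie in these pooled lists and none is about the spread between cultures. With 1 pooled list per condition, the effect of IAA on the number of regions has no replicate test.

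The alternatives were an overlap of 50% of both regions, summits within 200 bp, −log10 q of at least 5 or 10, fold of at least 5, single rows in place of joined regions, chromosomes 1 to 22 and X alone, equal numbers of the regions with the highest −log10 q, lists without regions called with all 4 antibodies in either condition, shifts of 10 to 100 kb, −log10 q as the strength of a region, and Mantel-Haenszel odds ratios over 5 strata of fold. These choices, the tests and the rule for named regions were fixed before the data were examined. The strata of CTCF fold, the summit distances, the odds of TET1 at CTCF regions with MBD3, the fold of kept MBD3 and TET2 regions and the counts near chromosome ends or per segment were added afterwards, as were the shares kept among the regions of highest −log10 q. Also added afterwards were the tests of fold at CTCF against away, the shares at CTCF of the strongest and weakest 10%, and the shares per chromosome. The rule took, for each antibody on chromosomes 1 to 22 and X, the 3 regions of highest fold among those called without IAA only, in both conditions and with IAA only, or every region where a class held 5 or fewer, and the 3 highest regions called with all 4 antibodies. For regions called in both conditions it was applied within each list. Coordinates are those of the lists, in hg19, counted from 1.

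The statistics were tested on simulated data. Of 5000 simulated regions with 40% placed at sites of a second list, 40.3% were recovered as shared, and 3.5% of 200 unrelated lists reached p of 0.05 or less. A loss with an odds ratio of 3 that was mixed with region strength came out as 0.919 without strata and as 2.82 over 5 strata. That simulation held 20000 regions, so it does not cover tests with as few kept regions as the 12 of MBD3 or 6 of TET2. The unrelated lists were placed at random without clusters, unlike the real lists. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6, numba 0.67.0 and matplotlib 3.10.9. The planned comparisons of promoters, CTCF motifs and gene lists, and the naming of the nearest gene, need an hg19 sequence or annotation and were not run, so regions are given by position only. The input samples were not analysed here as groups of their own.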

Results

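ChIP-seq peaks of CTCF, the zinc-finger protein that anchors chromatin loops, were compared in HEK293T cells without IAA and after 72 h with IAA, which triggers degradation of the tagged CTCF. The same was done for MBD3, a subunit of the nucleosome remodelling and deacetylase (NuRD) complex, and for TET1 and TET2, enzymes that oxidise methylated cytosine. The design asks which binding of the other proteins goes with CTCF. Each of the 8 peak lists pools the 3 samples of a group, so no list has a replicate error and the difference between conditions was not tested across cultures. The read depth of the lists is unknown. The longest list held 42925 regions, with a median width of 276 bp, and the shortest held 50.

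CTCF regions almost disappeared with IAA. The list went from 42925 regions without IAA to 63 with IAA, and 54 of the 42925 were still called, a share of 0.126% (Wilson 95% interval 0.0964% to 0.164%). Other settings gave shares from 0.0349%, at −log10 q of at least 10, to 17.5% between equal numbers of regions taken by −log10 q from each list. The 3 strongest regions that were no longer called lay at 58299121 to 58299535 on chromosome 12, 147553417 to 147553861 on chromosome 1 and 73121727 to 73122273 on chromosome 6, with 125.9-, 120.8- and 109.5-fold enrichment. TET1 and MBD3 had also been called at all 3 of these sites without IAA, and no antibody gave a region there with IAA. The 3 strongest kept regions, at 130879853 to 130880264 on chromosome 9, 30200585 to 30201197 on chromosome 20 and 90182581 to 90182958 on chromosome 16, ranked 19, 28 and 49 by fold in the list without IAA, at 94.7-, 85.0- and 80.1-fold. Within the list with IAA, the highest kept region lay at 112505276 to 112505505 on chromosome 2, at 10.97-fold, followed by 26690412 to 26690606 on chromosome 1 at 10.4-fold and 111496371 to 111496574 on chromosome 5 at 9.89-fold.

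The kept CTCF regions were mixed, with many strong regions and some weak ones. Their median fold without IAA was 33.8 (quartiles 24.9 and 46.2), against 13.6 (quartiles 7.43 and 24.2) for the 42871 regions no longer called, with a permutation p of 1e-05, the smallest that 100000 splits can give. The difference was no longer past the threshold when 50% of both regions had to overlap, at 4.57 (permutation p = 0.196). Of the 54 kept regions, 26 came from the strongest 10% of the list, of which 0.606% (0.414% to 0.886%) was kept. At the other end, 7 of the 54, or 13.0% (6.42% to 24.4%), had a fold under 3, against 0.648% of all CTCF regions. All 4 antibodies were called, in 1 condition or the other, at 8 of the 54. TET1 had been called at 52 of the 54 kept regions and MBD3 at 33. Just 9 CTCF regions were called with IAA only. The 3 with the highest fold lay at 61975553 to 61975940 on chromosome 7, 46432470 to 46432818 on chromosome 16 and 42395998 to 42396163 on chromosome 10, near centromeres. Their fold was 3.46, 2.05 and 1.77, and with IAA all 4 antibodies were called at each of them.

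**Figure D1:**
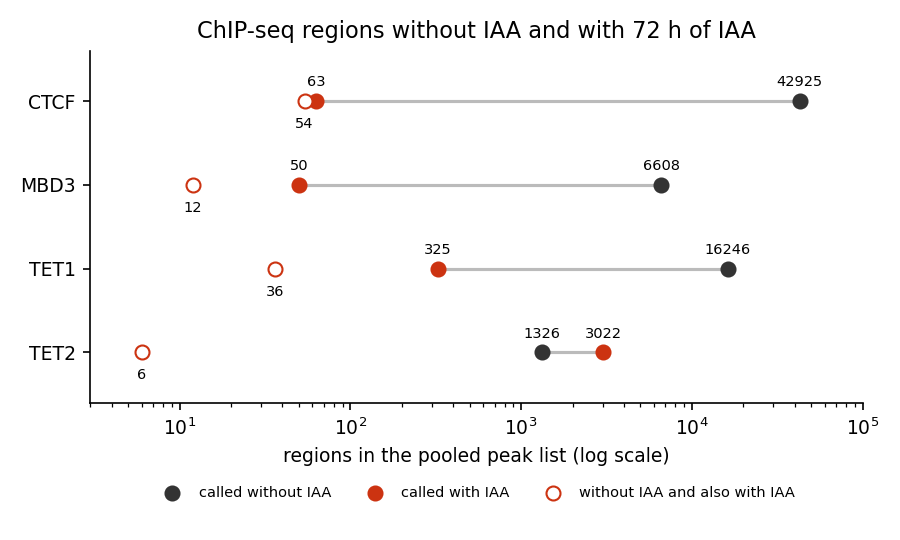
Number of regions in each pooled peak list (horizontal log axis) for the 4 antibodies, without IAA (black), with IAA (red), and called without IAA and again with IAA (open). CTCF, MBD3 and TET1 went from 42925, 6608 and 16246 regions to 63, 50 and 325, while TET2 went from 1326 to 3022, of which few lay at the earlier sites. Each point is 1 list with no replicate error.

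Without IAA, MBD3 and TET1 lay largely where CTCF did. Of 16246 TET1 regions, 14798 were at CTCF, or 91.1% (90.6% to 91.5%), against a mean of 0.766% for shifted regions, 119-fold more. Of 6608 MBD3 regions, 3727 were at CTCF, or 56.4% (55.2% to 57.6%), 77.2-fold more than the 0.731% of the shifts. TET2 was at CTCF less often, in 475 of 1326 regions, or 35.8% (33.3% to 38.4%), 47.1-fold more than the shifts. Each permutation p was 0.001, the smallest that 1000 shifts can give, and stayed so after adjustment over the 9 comparisons of lists. Shifts of 10 to 100 kb, which keep the neighbourhood of each region, lowered the folds to 75.1 for TET1, 51.2 for MBD3 and 31.1 for TET2. With 50% overlap of both regions the shares at CTCF were 67.2% for TET1, 24.9% for MBD3 and 20.4% for TET2. That rule depends on region width, and the median width was 276 bp for CTCF, 197 bp for TET1, 188 bp for MBD3 and 191 bp for TET2. With summits within 200 bp the shares were 90.2%, 55.3% and 30.2%, in the order TET1, MBD3 and TET2. Strong TET1 regions were at CTCF without exception: this held for all 1624 regions in the strongest 10% of the list and for 56.7% of the weakest 10%. For MBD3 these shares were 83.9% and 43.0%, and for TET2 32.6% and 37.6%.

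Seen from CTCF, the share of regions called with the other antibodies varied with the strength of the CTCF region. TET1 was called at 34.4% of the 42925 CTCF regions, MBD3 at 8.67% and TET2 at 1.10%, and 64.4% carried none of these. CTCF regions with TET1 had a median of 28.0-fold enrichment against 9.35-fold for those without TET1. With and without MBD3 the medians were 36.0 and 12.5. TET2 went the other way, with a median of 5.91-fold at CTCF regions that carried it and 13.6-fold at the others. Each permutation p, adjusted over the 3 proteins, was 1e-05, the smallest these splits can give. Over 10 strata of CTCF fold, the share with TET1 was 7.87% in the weakest stratum, 4.26% at its lowest and 96.7% (96.2% to 97.2%) in the strongest. For MBD3 it was 4.75% in the weakest stratum, 0.862% at its lowest and 45.4% (43.9% to 46.9%) in the strongest. The share with TET2 was 4.22% in the weakest stratum, 0.256% (0.143% to 0.458%) at its lowest, in stratum 9, and 1.00% (0.745% to 1.35%) in the strongest.

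**Figure D2:**
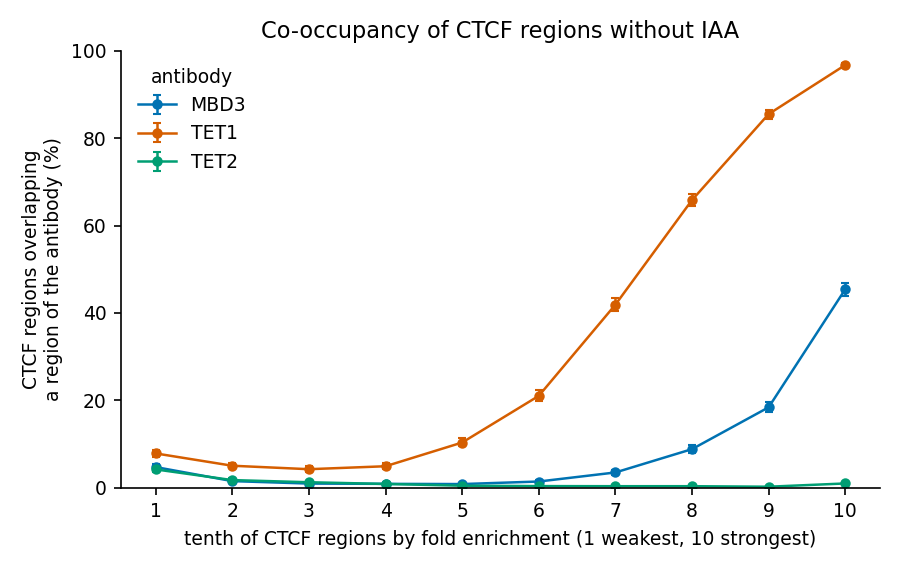
Share of CTCF regions without IAA that overlapped a region of MBD3, TET1 or TET2 (vertical axis, percent) in 10 equal strata of the CTCF list ordered by fold enrichment (horizontal axis, 1 weakest and 10 strongest). Bars are Wilson 95% intervals; TET1 reached 96.7% and MBD3 45.4% in the strongest stratum, while TET2 stayed at or under 4.22% throughout.

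Shared regions were centred on the CTCF summit for TET1 and MBD3. The median distance to the nearest CTCF summit was 7 bp for TET1 (quartiles 3 and 13) and 12 bp for MBD3 (quartiles 5 and 23), and 96.1% and 89.7% of these regions lay within 50 bp. TET2 summits lay farther off, at a median of 75 bp (quartiles 31 and 152), with 36.6% within 50 bp.

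**Figure D3:**
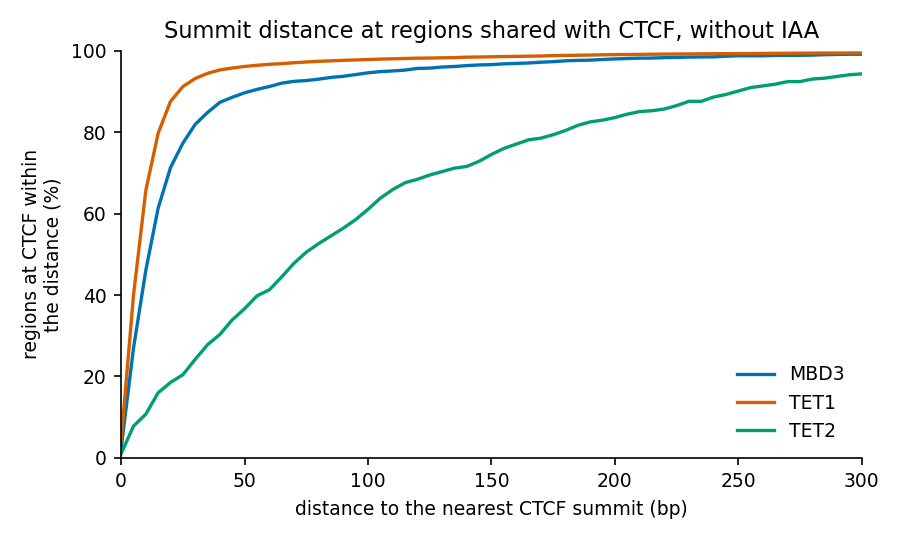
Cumulative share of the MBD3, TET1 and TET2 regions at CTCF without IAA (vertical axis, percent) by distance from their summit to the nearest CTCF summit (horizontal axis, bp). The median was 7 bp for TET1, 12 bp for MBD3 and 75 bp for TET2.

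MBD3 and TET1 also went together. Of the MBD3 regions, 57.1% (55.9% to 58.3%) carried TET1, 131-fold more than shifted regions. At CTCF 90.5% of MBD3 regions carried TET1, and away from CTCF 13.9% did. Among CTCF regions, TET1 was called at 90.7% of those with MBD3 and at 29.0% of those without, an odds ratio of 23.8 (95% interval 21.3 to 26.6), which was 6.66 (5.69 to 7.80) over 10 strata of CTCF fold. TET2 was rarer, at 6.33% of MBD3 regions and 2.78% of TET1 regions, 33.0- and 30.0-fold more than the shifts. At −log10 q of at least 5 these shares were 3.67% and 1.02%. All 4 antibodies were called at 140 regions, against a mean of 0.003 for the shifts (permutation p = 0.001, the smallest possible). At −log10 q of at least 5 there were 37 such regions. The 3 with the highest CTCF fold lay at 58299121 to 58299535 on chromosome 12, 172571264 to 172571745 on chromosome 5 and 41560911 to 41561472 on chromosome 17. In the CTCF list they stood at 125.9-, 95.7- and 86.2-fold, in the MBD3 list at 11.6-, 9.05- and 11.6-fold, in the TET1 list at 32.9-, 17.7- and 21.5-fold, and in the TET2 list at 4.55-, 4.17- and 4.76-fold.

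MBD3 regions were nearly absent with IAA. The list went from 6608 regions to 50, and 12 of the 6608 were kept, or 0.182% (0.104% to 0.317%). At a fold of at least 5 the share was 0.0%, and between equal numbers of regions taken by −log10 q it was 14.0%. The strongest regions that were no longer called lay at 25314153 to 25314579 on chromosome 4, 23866361 to 23866592 and 66708420 to 66708649 on chromosome 1, at 16.7-, 14.4- and 14.0-fold, each with CTCF and TET1 without IAA. All 12 kept regions had a fold under 3 without IAA, near the bottom of the list by fold. The highest on chromosomes 1 to 22 and X, at 27731965 to 27732321 on chromosome 19, ranked 6566 by fold, at 2.12, with a −log10 q of 248. It was followed by 42400209 to 42400706 on chromosome 10 at 2.098-fold and 67320522 to 67320886 on chromosome 9 at 1.83-fold. All 4 antibodies had been called at each of these without IAA. Within the list with IAA the highest of the kept regions were the same region on chromosome 19 at 2.16-fold, 92316210 to 92316771 on chromosome 2 at 2.16-fold and the region on chromosome 9 at 1.99-fold. Of the 660 regions in the top 10% by fold, 0 were kept, with an upper bound of 0.579%, and of the 660 in the top 10% by −log10 q 11 were, or 1.67% (0.933% to 2.96%).

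MBD3 regions went uncalled both at CTCF sites and away from them. With 50 regions in the list with IAA, few of either class could have been kept, so near-complete loss in both was set by the length of that list. At CTCF 5 of 3727 MBD3 regions were kept, and away from CTCF 7 of 2881, shares of 0.134% (0.0573% to 0.314%) and 0.243% (0.118% to 0.501%). The odds ratio of loss at CTCF to away was 1.81 (0.575 to 5.72, Fisher's exact p = 0.386, adjusted p over the 3 proteins 0.429), so no difference was detectable with 12 kept regions. Its direction turned over 5 strata of fold (0.945) and with 50% overlap of both regions (0.265, Fisher's exact p = 0.0481). All 12 kept regions had a fold under 3 and so fell in the weakest of the 5 strata, on which the 0.945 rests alone. The 50% rule also changed the classes. It counted 1646 MBD3 regions as at CTCF in place of 3727, and the others that touched CTCF as away. Neither turn is read as a reversal. Leaving out regions called with all 4 antibodies, which without IAA lie at CTCF by definition, took away all 5 kept regions at CTCF and none of the 7 away, so the 18.7 that results (1.07 to 328, Fisher's exact p = 0.00345), although past the threshold, is set by that filter. The 38 MBD3 regions called with IAA only lay at former CTCF sites in 1 case, against 5 of the 12 kept regions (odds ratio 0.0378, 0.00382 to 0.375), and with that filter the odds ratio was 0.692. Its direction is largely set by the definition of the classes: regions called with IAA only lie, by construction, outside the earlier MBD3 regions and so outside the CTCF sites those covered. The same holds for TET1 and TET2, and no p-value is given for these comparisons. The strongest regions called with IAA only lay at 105668146 to 105668340 and 110807589 to 110807765 on chromosome 10 and 126096095 to 126096321 on chromosome 11, at 7.19-, 6.33- and 6.12-fold.

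TET1 followed the same course. The list went from 16246 regions to 325, and 36 of the 16246 were kept, or 0.222% (0.160% to 0.307%). At a fold of at least 5 it was 0.0611%, and between equal numbers of regions taken by −log10 q it was 4.0%. The strongest regions no longer called lay at 17875591 to 17876396 and 45973080 to 45973665 on chromosome 17, with CTCF, and at 147553515 to 147553862 on chromosome 1, with CTCF and MBD3, at 40.8-, 40.3- and 38.1-fold. The kept regions with the highest fold without IAA lay at 70506835 to 70507063 on chromosome 6, 56367408 to 56367862 on chromosome 12 and 86375456 to 86375658 on chromosome 8, at 18.8-, 18.4- and 16.1-fold. CTCF had been called at all 3 without IAA and at none with IAA. Within the list with IAA the highest kept regions lay at 87303582 to 87303778 on chromosome 2, 104166947 to 104167157 on chromosome X and 116661956 to 116662346 on chromosome 11, at 7.62-, 6.12- and 6.02-fold. At CTCF 30 of 14798 TET1 regions were kept and away from it 6 of 1448, an odds ratio of loss of 2.05 (0.851 to 4.93, Fisher's exact p = 0.131, adjusted p = 0.393). It passed the threshold at −log10 q of at least 5 (16.9, Fisher's exact p = 0.000317) and turned with 50% overlap of both regions (0.683). The 50% rule also counted some regions that touched CTCF as away, leaving 10922 at CTCF, so this turn of the odds ratio is not read as a reversal. Without regions called with all 4 antibodies it was 2.77 (Fisher's exact p = 0.0351), also past the threshold, but again because the filter took kept regions from the CTCF side alone, from 30 to 22, and left 6 away.

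Few of the TET1 regions that appeared with IAA lay at former CTCF sites, but their share was above the mean of 0.766% for shifts of the TET1 list without IAA. The regions called with IAA only were not themselves shifted. Of the 289 called with IAA only, 15 were at former CTCF sites, or 5.19% (3.17% to 8.39%), against 30 of the 36 kept regions, an odds ratio of 0.0109 (0.00395 to 0.0303). The odds ratio was between 0.00382 and 0.0179 in the other settings. The strongest of them lay at 33887627 to 33887789 on chromosome 16, 7174949 to 7175287 on chromosome 1 and 147551695 to 147551883 on chromosome 1, at 11.8-, 8.65- and 7.71-fold. TET2 was also called at the first of these with IAA.

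TET2 was the exception in number. Its list went from 1326 regions to 3022, yet the regions were almost all different ones: 6 of the 1326 were kept, or 0.452% (0.208% to 0.984%). At a fold of at least 5 it was 0.0%, and at −log10 q of at least 10 it was 1.89%. The strongest regions no longer called lay at 174219127 to 174219618 and 44588911 to 44589344 on chromosome 2 and 228674573 to 228675064 on chromosome 1, at 45.3-, 43.0- and 39.0-fold, and CTCF had been called at none of them. On chromosomes 1 to 22 and X the kept regions numbered 5. They lay at 236260429 to 236260637 on chromosome 1, 10170 to 11687 on chromosome 5, 17109783 to 17109928 on chromosome 17, 567290 to 567440 on chromosome 1 and 92316229 to 92316686 on chromosome 2, at 3.09-, 2.80-, 2.68-, 2.42- and 1.50-fold without IAA. Loss did not differ detectably between regions at CTCF (1 of 475 kept) and away (5 of 851 kept), with an odds ratio of 2.80 (0.326 to 24.0, Fisher's exact p = 0.429, adjusted p = 0.429), and its direction turned with 50% overlap of both regions (0.770). That rule also left 271 TET2 regions at CTCF in place of 475.

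Of the 3016 TET2 regions called with IAA only, 34 were at former CTCF sites, or 1.13% (0.808% to 1.57%). Shifts of the TET2 list without IAA gave a mean of 0.761%, and the regions called with IAA only were not themselves shifted. Of the 6 kept regions 1 was at such a site, an odds ratio of 0.0570 (0.00649 to 0.501), which was 0.0120 with 50% overlap of both regions and 0.0238 at −log10 q of at least 5. It was weaker, at 0.127 (0.00690 to 2.35), with summits within 200 bp. Without regions called with all 4 antibodies it was 0.127 (0.00691 to 2.35). In both of these settings 0 of 5 kept regions were at former CTCF sites. The strongest regions called with IAA only lay at 131962095 to 131962272 on chromosome 12, 186748197 to 186749196 on chromosome 4 and 33887422 to 33887794 on chromosome 16, at 19.8-, 18.7- and 16.8-fold. Many of the TET2 regions with IAA lay toward the ends of chromosomes: 976 of the 2897 on chromosomes 1 to 22 and X, or 33.7% (32.0% to 35.4%), were within 5 Mb of an end. For TET2 without IAA this share was 8.65% (7.24% to 10.3%) and for CTCF without IAA it was 9.20%. The end segments make up 7.58% of the length up to the highest listed positions, which can include stretches where no region can be called. The odds ratio between the TET2 lists was 5.37 (4.36 to 6.61, Fisher's exact p = 8.02e-75). That test counts regions as independent, although 28.2% of them with IAA and 12.1% without had another region within 10 kb. Its interval is therefore too narrow and its p too small. The other lists with IAA also had larger shares near ends than without it, differences that were not tested: 27.2% (22.6% to 32.4%) against 9.27% for TET1, 20.6% (12.5% to 32.2%) against 9.20% for CTCF and 17.4% (9.09% to 30.7%) against 6.39% for MBD3. Chromosomes 16, 2 and 4 also held clusters, with 53 regions between 46 and 48 Mb, 48 between 90 and 92 Mb and 48 between 48 and 50 Mb. The segment on chromosome 16 contains a CTCF region described above as near a centromere. With IAA it also held 20 TET1, 2 MBD3 and 2 CTCF regions, and the segments on chromosomes 2 and 4 held 2 TET1 regions each. Distances from centromeres were not measured, so the segments on chromosomes 2 and 4 may also lie near them.

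**Figure D4:**
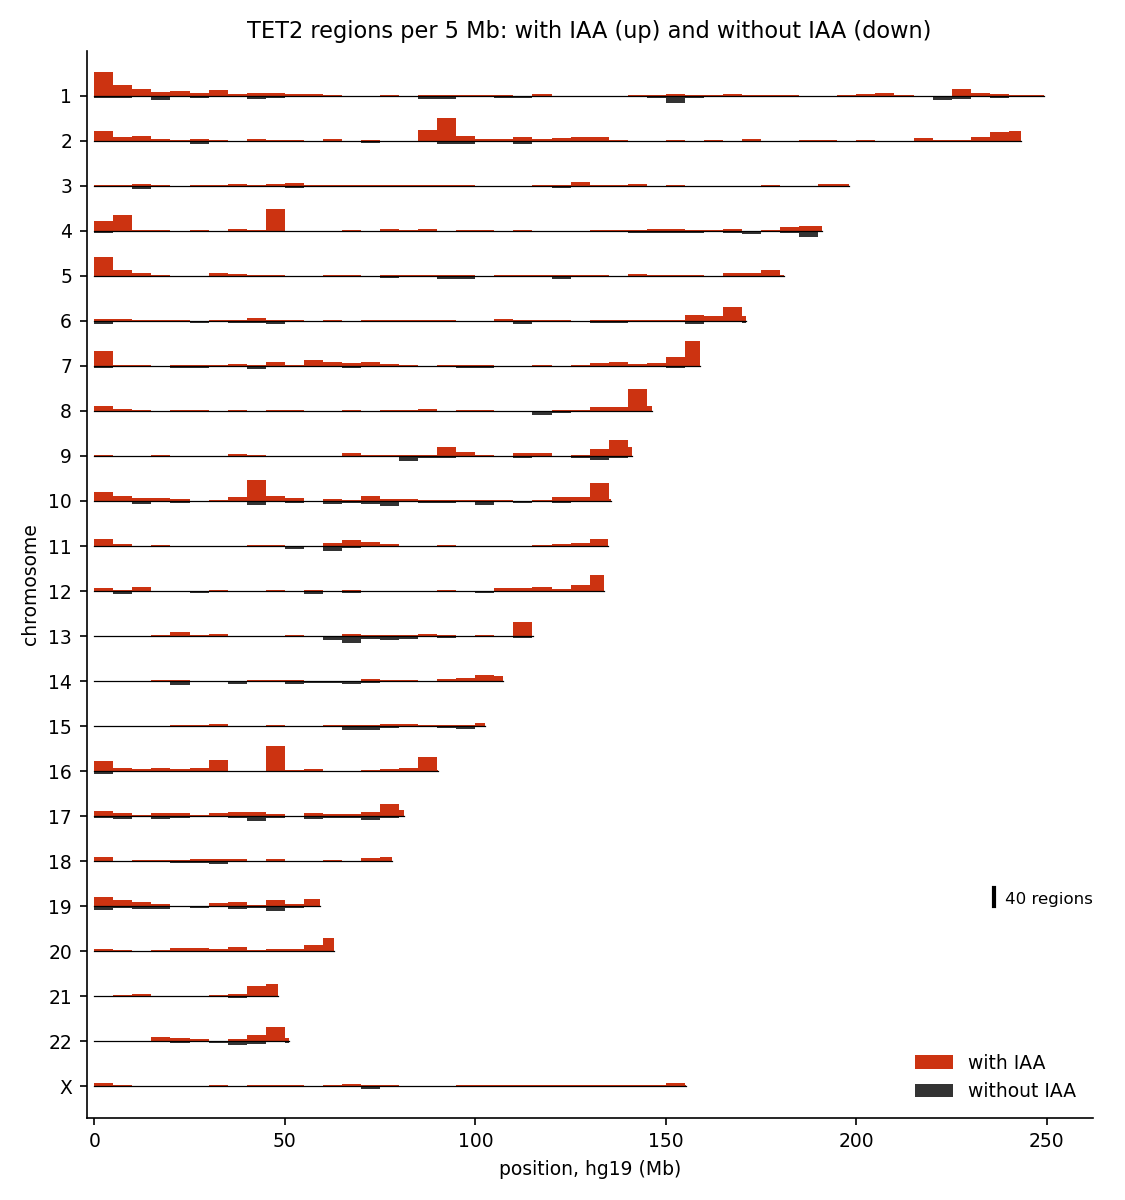
TET2 regions per 5 Mb along chromosomes 1 to 22 and X in hg19 (horizontal axis, Mb), with IAA (red, upward) and without IAA (black, downward), both on the scale of the bar for 40 regions. With IAA the counts reached 55 in 2 segments, at 155 to 160 Mb on chromosome 7 and at 45 to 50 Mb on chromosome 16, and without IAA 16, at 65 to 70 Mb on chromosome 13.

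With IAA the few regions of the other antibodies often coincided. TET1 was called at 31 of the 50 MBD3 regions, or 62.0% (48.2% to 74.1%), and TET2 at 20 of them, or 40% (27.6% to 53.8%). TET2 was called at 126 of the 325 TET1 regions, or 38.8% (33.6% to 44.2%). These shares were 144-, 32.4- and 86.5-fold above the shifts, each with a permutation p of 0.001, the smallest possible. With shifts of 10 to 100 kb the folds were 185, 24.1 and 29.0 in the same order. With 50% overlap of both regions the share of MBD3 regions with TET2 was 26.0%, and at −log10 q of at least 5 the share of TET1 regions with TET2 was 69.7%. All 4 antibodies were called at 5 regions with IAA, and at 3 when −log10 q was at least 5. The 5 lay at 61975452 to 61975962 on chromosome 7, 46432244 to 46432857 on chromosome 16, 42395977 to 42396206 and 42596889 to 42597194 on chromosome 10 and 55625904 to 55626833 on chromosome 19, and in the CTCF list their fold was between 1.28 and 3.46. Regions of fold under 3 made up 30 of the 50 MBD3 regions with IAA, 18 of the 63 CTCF regions and 93 of the 325 TET1 regions.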

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

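The tests of weak regions, of lower yield, of sites called with any antibody, of shared background, of chromosome ends and of unplaced sequence were chosen after the result was seen.

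The difference between antibodies in the response to IAA stood out. With IAA the number of regions was 0.147% of that without IAA for CTCF, 0.757% for MBD3 and 2.00% for TET1, but 228% for TET2, so that 3 lists shrank and 1 grew. With 1 pooled list per antibody and condition the difference was not tested.

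The TET2 regions called with IAA lay elsewhere than those called without it. Mitochondrial, unplaced and haplotype sequence, with the other contigs outside chromosomes 1 to 22 and X, held 4.14% of them (3.48% to 4.91%), which argues against such sequence as the main source. Background near chromosome ends may account for part of the list, as 33.7% lay within 5 Mb of an end, leaving 66.3% elsewhere. With IAA the share near ends was also 27.2% for TET1, 20.6% for CTCF and 17.4% for MBD3. The regions elsewhere included clusters, among them 53 regions between 46 and 48 Mb on chromosome 16, near a centromere. The share of the list near centromeres was not measured. Background shared by the antibodies with IAA may account for part as well: 44.0% (38.8% to 49.5%) of the TET1 and MBD3 regions called only with IAA lay in TET2 regions, although 4.14% of the TET2 regions carried either protein. A redistribution of TET2 after CTCF loss, the difference the design names, stays open and untested.

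TET1 regions coincided with CTCF regions in 91.1% of cases. Sites called with any antibody whatever CTCF does are 1 explanation, on which TET2 with IAA, the list that did not shrink, does not decide. With IAA few such sites were called for TET2: 0.529% (0.326% to 0.858%) of its 3022 regions lay at TET1 regions at CTCF. Only 1.16% of that list lay at any former CTCF site, so a large share was not possible. Without IAA 19.5% (17.4% to 21.7%) of the 1326 TET2 regions lay at TET1 regions at CTCF. Shifted TET2 regions were at CTCF in 0.761%, so the 19.5% does not argue against such sites. Seen from TET1, without IAA 1.74% (1.54% to 1.97%) of its regions at CTCF carried TET2, against 13.4% away. TET2 was called at 1.00% (0.745% to 1.35%) of the strongest 10% of CTCF regions. These values argue against such sites as the source of most TET1 regions at strong CTCF regions. The TET2 list was short and its depth is unknown, so some such sites stay possible. CTCF brought down in the TET1 immunoprecipitation, by cross-reaction or by crosslinked complexes, could give the near-complete TET1 calls at the strongest 10% of CTCF regions, 96.7% (96.2% to 97.2%). TET1 bound at these sites because of CTCF would give the same share, so this value does not separate the 2 readings. Both stay open. The same 2 readings stay open for MBD3 at CTCF. MBD3 was called at 45.4% (43.9% to 46.9%) of the strongest 10% of CTCF regions. Over all MBD3 regions at CTCF, the median distance between the summits was 12 bp. Of these MBD3 regions 90.5% carried TET1, which CTCF brought down in both immunoprecipitations could also give. This was not tested.

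MBD3 regions away from CTCF went uncalled with IAA as those at CTCF did. CTCF sites that missed the CTCF threshold stay open. MBD3 was called at 3.15% (2.80% to 3.54%) of the weakest 20% of CTCF regions, below the 7% set beforehand, but the share rose toward the threshold, from 1.54% in the second weakest 10% to 4.75% (4.15% to 5.43%) in the weakest, so it sets no limit for sites below it. The fall of weak regions under the threshold stays open as well. Of the top 20% by fold away from CTCF 0.0% was kept, and of the top 20% by −log10 q 1.22% (0.590% to 2.49%), but with 50 regions in the list with IAA neither share of 576 regions had room to be large. A lower yield of the MBD3 immunoprecipitation with IAA cannot be told apart from a wider effect of CTCF loss, since the odds ratio of loss at CTCF to away, 1.81 (0.575 to 5.72), rests on 12 kept regions. The culture effect of IAA itself was not tested, because no sample without the tag was analysed here.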

How the results depend on the processing

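No paired analysis was possible because each list pools its 3 replicates, and for the same reason no replicate was left out. The promoter, motif and gene-list comparisons were not run with any setting. Of 155 values under other settings, 118 kept the direction and the side of the threshold or stayed within the interval (1.5 times for counts). The 42 on sharing between lists are among these because each p was the smallest possible, which says little of stability. The share of MBD3 regions at CTCF went from 56.4% to 24.9% with 50% overlap of both regions, a rule that depends on region width. It was 55.3% with summits within 200 bp and 73.7% at −log10 q of 5. The depth of the lists is unknown and limits how the numbers of regions can be compared.

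The share of regions kept moved as follows. For CTCF (0.126%) it was 0.0443% with 50% overlap of both regions, 0.0652% at −log10 q of at least 5, 0.0349% at 10, 0.0957% at fold of at least 5 and 17.5% with equal numbers of regions taken by −log10 q. For MBD3 (0.182%) it was 0.791% at −log10 q of 10, 0.0% at fold of 5, 0.386% with single rows and 14.0% with equal numbers. For TET1 (0.222%) it was 0.0788% and 0.0756% at −log10 q of 5 and 10, 0.0611% at fold of 5 and 4.0% with equal numbers. For TET2 (0.452%) it was 1.08% and 1.89% at −log10 q of 5 and 10 and 0.0% at fold of 5. Equal numbers compare fewer regions by construction.

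The number with IAA as a percentage of that without became 0.0777, 0.0465 and 0.0957 for CTCF at −log10 q of 5 and 10 and fold of 5. For TET1 it became 0.638, 0.510 and 0.596 in that order. For MBD3 it became 1.78 at −log10 q of 10 and 0.218 at fold of 5.

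The odds ratio of loss turned with 50% overlap to 0.265 for MBD3, 0.683 for TET1 and 0.770 for TET2, and over strata of fold to 0.945 for MBD3. The 50% rule also counted regions that touched CTCF as away, and the 0.945 rests on the weakest stratum alone. The odds ratio passed the threshold at −log10 q of 5 for TET1 (16.9). Without regions called with all 4 antibodies it also passed, at 18.7 for MBD3 and 2.77 for TET1, but these values are set by a filter that took kept regions from the CTCF side alone. Regions called with IAA only against kept ones, a contrast whose direction their definition largely sets, gave 0.692 for MBD3 with the same filter. For TET2 they gave 0.0120 with 50% overlap and 0.0238 at −log10 q of 5, but 0.127 with summits within 200 bp and also with the same filter. Fold of kept against lost CTCF regions differed by 4.57 with 50% overlap, no longer past the threshold. Regions called with all 4 antibodies numbered 37 without and 3 with IAA at −log10 q of 5. The cause was not tested.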

Other observations

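Regions of MBD3, TET1 and TET2 away from CTCF had the same densest segment without IAA. The 2 Mb between 66 and 68 Mb on chromosome 13 held 43 of the 2881 MBD3, 38 of the 1448 TET1 and 9 of the 851 TET2 regions away from CTCF, the most of any such segment for each protein, while CTCF had 36 regions there. With IAA none of CTCF, MBD3 and TET1 was called in that segment, and TET2 was called 2 times. With 63, 50 and 325 regions in the first 3 of these lists, few could fall in any 1 segment, so their absence says little about it. The next segments for MBD3 lay between 124 and 126 Mb on chromosome 5, with 19, and between 76 and 78 Mb on chromosome 10, with 17. These segments were chosen after their counts were seen.

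By chromosome, the shares of regions away from CTCF departed from those of CTCF regions, for MBD3 and for the other proteins. For MBD3, chromosomes 4, 5, 6, 10 and 13 held 8.02%, 8.12%, 10.2%, 9.93% and 6.94% of the regions away from CTCF, against 5.06%, 5.54%, 5.78%, 4.61% and 2.63% of CTCF regions. Chromosomes 16, 17, 19 and 22 held 0.625%, 2.26%, 0.798% and 0.451%, against 3.35%, 4.61%, 4.05% and 2.04% of CTCF regions. For TET1, chromosomes 5, 6, 10 and 13 held 7.39%, 7.94%, 8.63% and 9.32% of the regions away from CTCF, and chromosomes 19 and 22 held 1.66% and 0.414%. For TET2, chromosomes 4 and 10 held 8.46% and 8.23%. No test was run on these shares, and copy number of the chromosomes in this line was not examined.

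MBD3 and TET1 regions away from CTCF were weaker than those at CTCF, with median folds of 5.00 against 5.91 for MBD3 and 4.22 against 7.61 for TET1. TET2 regions away from CTCF were slightly stronger, at 4.76 against 4.46. The permutation p, adjusted over the 3 proteins, was 1.5e-05 for MBD3 and TET1, whose raw p of 1e-05 is the smallest the splits can give, and 0.00799 for TET2. TET2 was called at 9.23% of MBD3 regions away from CTCF and 4.08% of those at CTCF, and at 13.4% and 1.74% of TET1 regions.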
